A study of Mus musculus with 9 samples.

How the data were processed

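RNA of adult mouse cardiac fibroblasts, dedifferentiated cardiac fibroblasts and ES cells was hybridised to 9 one-colour Affymetrix Mouse Gene ST arrays (version 1.0, per the labels). The deposited values are log2 expression values; per the submitters' processing notes they were made with RMA in Affymetrix Expression Console 1.1. As a method, RMA corrects background, quantile-normalizes the probes over the arrays and summarises each probe set, so a general rise or fall of all transcripts would not be seen and changes of dim genes are understated. The values carry no detection call, so low values are not set against a background level. The table has 35557 rows and no further columns.

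Groups were taken from the sample titles. The source label of the fibroblast samples also mentions ES cells; the titles were followed. No 2 arrays held identical values. Exactly equal values on 3 arrays occurred in 363 to 789 rows for arrays of 1 group and in 283 to 620 rows for arrays of different groups, so an SD close to 0 for a gene is not a measure of its precision.

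Rows were named through the platform annotation: 21789 rows had 1 gene symbol, 1621 had several and 12147 were not listed there. Of the rows with 1 symbol, 21698 matched the NCBI gene table of assembly GRCm38.p6 by Entrez ID, and 0 symbols changed. No gene was named from a row with several symbols; Cdkn1a, H19 and Ddx3y had no row with 1 symbol and are not reported here. Where a gene had more than 1 row (999 genes), the row with the highest mean over all arrays was used, leaving 19938 genes; of the genes named, only Dppa2 and Zc3h6 had more than 1 row, and their rows changed the same way.

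All 9 arrays entered 1 limma fit (limma 3.58.1, R 4.3.3) with empirical Bayes moderation. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1 log2 unit. Differences are group means subtracted in the order named, with 95% intervals from the fit. Gene lists (28, holding 535 places of which 493 had a row) were written before the data were examined, as were the tests and alternatives, and were tested with camera at a preset correlation of 0.01, adjusted over 84 tests. A moderated F test compared the 3 groups. The position of an array was the least-squares slope of its difference from the fibroblast mean on the ES minus fibroblast difference, with an exact permutation test. The correlation of changes was set beside 100 simulations of unchanged groups.

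Genes were named by a rule written before the data were examined. It takes, per comparison, the 6 largest rises and 6 largest falls among called genes whose arrays do not overlap, leaving out clone and model names and genes whose row matches another gene; the 2 called members of each list with the largest rise and the 2 with the largest fall, or the member with the smallest p where none was called; and 20 genes fixed in advance. Otx2, Cd44 and Runx1 fall outside it in the comparison with ES cells and were named after their values were seen, as were Eif2s3x, Kdm6a and the genes named only in the closing section.

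The fit was tested on simulated data with the real genes' means and spread and 200 changed genes. For each comparison, 67 of 67 genes changed by 1.5 log2 units and 66 of 66 changed by 3 were called, 0 of 67 changed by 0.5 were, and 0 unchanged genes were called, in a step run on 19938 genes.

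Alternatives were another quantile normalization, median centring, 2 filters on dim genes, all rows of the table, the mean of a gene's rows, an intensity trend, robust variances, array weights, a fit of only the 2 groups compared, the replicate number as a block, leaving out each array, other thresholds, an estimated correlation and fry for the lists, other genes or linear values for the position, and a margin of 1.5-fold for equivalence.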

Results

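The study compared the RNA of 3 kinds of mouse cells labelled C57BL/6: adult cardiac fibroblasts, cells described as such fibroblasts after a protein-based dedifferentiation, and embryonic stem (ES) cells. Each group had 3 samples, and each sample was read on 1 Affymetrix Mouse Gene ST array, giving 9 arrays and 35557 probe-set values per array. The median log2 value of an array lay between 4.647 and 4.859. Pairs of arrays correlated at 0.9907 to 0.9942 among fibroblasts, 0.9931 to 0.9946 among dedifferentiated cells and 0.9875 to 0.9923 among ES cells. Fibroblast arrays correlated with dedifferentiated arrays at 0.9151 to 0.9234, and dedifferentiated arrays with ES arrays at 0.9818 to 0.9863. The labels do not say whether the samples of a group came from separate animals or cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical, and the 3 arrays per group limit the precision. The camera p-values compare a list's genes with all other genes, and the p-values of chromosomes compare their genes with random gene lists. Neither measures a spread between animals or cultures.

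The first comparison asked how the dedifferentiated cells differed from the fibroblasts. Genes of the pluripotent state were far higher in the dedifferentiated cells, and genes of connective tissue and inflammation were far lower. Tdgf1, a Nodal co-receptor of early embryonic cells, rose by 8.39 log2 units (335-fold, 95% interval 8.17 to 8.6). Pou5f1, which encodes the transcription factor Oct4, rose by 7.82 (7.28 to 8.37), from 3.39 ± 0.68 to 11.21 ± 0.038 (log2 mean ± SD, n = 3 each). Mmp3, a matrix-degrading protease, fell by 8.27 log2 units (95% interval -8.61 to -7.93), from 12.31 ± 0.083 to 4.04 ± 0.23 (n = 3 each). Of 19938 genes, 1753 were higher and 2012 lower by at least 1 log2 unit.

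Of 36 measured core pluripotency genes, 35 were higher in dedifferentiated cells than in fibroblasts, with a median change of 4.21 log2 units (camera adjusted p = 1.6e-23, and adjusted p = 0.0069 with an estimated correlation). Nanog rose by 6.69, Sox2 by 6.24, Esrrb by 5.48, Lin28a by 4.38 and Zfp42 by 2.98 log2 units. Dppa5a and Nr0b1, both typical of ES cells, rose by 7.31 and 7.06. Klf4 differed by 0.62 (95% interval 0.4 to 0.83), below the size required for a call. Myc, which is often delivered with Pou5f1, Sox2 and Klf4 to reprogram cells, differed by -0.84 (-1.04 to -0.64). Of 14 primed epiblast genes, 8 were higher, led by the DNA methyltransferase Dnmt3b at 4.85 and the claudin Cldn6 at 4.61; the list's adjusted p was 6.1e-05, and the adjusted p = 0.16 with an estimated correlation. Of 18 measured genes of 2-cell-like and germ cells, 10 were higher (adjusted p = 3.4e-05, and adjusted p = 0.023 with an estimated correlation), among them Tdrd12 at 5.44 and Rhox9 at 3.76. The 2-cell-like genes Zscan4c, Zscan4f and Tcstv1 of that list had no row with 1 symbol and were not measured. Trh, the precursor of thyrotropin-releasing hormone, rose by 7.27.

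Of 33 extracellular matrix genes, 31 were lower in the dedifferentiated cells and 0 higher (median -4.36, adjusted p = 1.6e-23, and adjusted p = 0.0069 with an estimated correlation). The fibrillar collagens Col3a1 and Col1a1 differed by -6.67 and -5.47 log2 units, and the collagen cross-linking enzyme Lox by -6.81. Of 27 genes of fibroblast and mesenchymal identity, 23 were lower (median -2.29, adjusted p = 3.9e-17, and adjusted p = 0.0069 with an estimated correlation). Pdgfrb fell by 5.66, S100a4 fell by 5.04 and the surface antigen Thy1 fell by 1.88. Of 12 cardiac transcription factors, 5 were lower, with Tcf21 down 99.2-fold and Tbx18 down 42.4-fold; the list's adjusted p was 0.012, and the adjusted p = 0.079 with an estimated correlation. That call was also lost among genes above the median level (adjusted p = 0.094) and among genes with a group mean of at least 6 (adjusted p = 0.15). Of 15 genes of myofibroblasts and smooth muscle, 10 were lower and 1 higher (adjusted p = 1.7e-07, and adjusted p = 0.062 with an estimated correlation). Acta2 fell by 3.72 and Tagln fell by 3.76, whereas Des rose by 1.33.

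Inflammatory and interferon genes were lower as well. Of 16 cytokine and chemokine genes, 13 were lower and 1 higher (median -3.43, adjusted p = 9.7e-09, and adjusted p = 0.032 with an estimated correlation): Ptx3 fell by 7.47, Il6 fell by 7.46, and Cxcl10 rose by 1.48. Of 18 interferon response genes, 17 were lower (median -2.67, adjusted p = 2.9e-12, and adjusted p = 0.026 with an estimated correlation), with Irf7 at -5.68 and Ifit1 at -5.21. Class I antigen presentation had 5 of 9 genes lower, including B2m at -2.66, with an adjusted p = 0.0033 for the list and an adjusted p = 0.062 with an estimated correlation. Of 18 genes in the list for TGF-beta, BMP and YAP, 16 were lower (adjusted p = 2.8e-11, and adjusted p = 0.022 with an estimated correlation), led by Tgfb3 at -5.45 and Inhba at -4.89. The list mixes targets with ligand genes, and Tgfb3 and Inhba are ligand genes. The acute-phase protease inhibitor Serpina3n fell by 7.52, the aggrecanase Adamts5 fell by 7.36 and the retinaldehyde dehydrogenase Aldh1a1 fell by 7.22.

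Epithelial, replication and chromatin genes were higher. Of 17 genes of epithelial junctions and keratins, 16 rose (median 2.98, adjusted p = 4.4e-12, and adjusted p = 0.022 with an estimated correlation), with Epcam up by 6.23 and the adhesion protein Cdh1 by 5.97. Of 24 genes of DNA replication, 16 were higher, including Mcm10 at 2.26 (adjusted p = 2.3e-08 for the list, and adjusted p = 0.15 with an estimated correlation). Of 20 mitosis genes, 8 were higher, led by Bub1 at 1.83 (adjusted p = 3.3e-08, and adjusted p = 0.21 with an estimated correlation). Of 25 chromatin and DNA methylation genes, 14 were higher and 1, Bmi1, was lower at -2.18 (adjusted p = 1.3e-09, and adjusted p = 0.07 with an estimated correlation). Of 11 telomere genes, 6 were higher, Rif1 most at 3.23 (adjusted p = 7.7e-06, and adjusted p = 0.13 with an estimated correlation). The glucose transporter Slc2a3 rose by 5.96 and 3 of 14 glycolysis genes were called; that list's adjusted p of 0.045 passed 0.05 without fibroblast replicate 1 (0.055) or 2 (0.069), dedifferentiated replicate 1 (0.056) or ES replicate 1 (0.057), and was an adjusted p = 0.51 with an estimated correlation. It was 0.056 to 0.18 with either filter on dim genes, all rows of the table, the mean of a gene's rows, array weights or only the 2 groups compared.

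Markers of other cells gave smaller and mixed changes between dedifferentiated cells and fibroblasts. Of 16 macrophage and haematopoietic genes, 6 were lower and 2 higher; Lyz2 fell by 5.65 and C1qc fell by 1.98 (adjusted p = 0.001 for the list, and adjusted p = 0.063 with an estimated correlation). That list lost its call and turned direction among genes above the median level (median 1.02, adjusted p = 0.6), and lost it among genes with a group mean of at least 6 (adjusted p = 0.74). The 2 higher genes, Cd68 at 1.05 and Laptm5 at 1.02, were below the required size without fibroblast replicate 2 for Cd68 (0.999), and without fibroblast replicate 3 (0.93) or dedifferentiated replicate 3 (0.95) for Laptm5. The lists for endothelium (6 of 13 higher, 2 lower, adjusted p = 0.11), cardiomyocytes (2 of 15 higher, adjusted p = 0.2), mesoderm and endoderm (5 of 19 higher, adjusted p = 0.071), trophoblast (5 of 12 higher, 1 lower, adjusted p = 0.065) and neural ectoderm (2 of 15 higher, 2 lower, adjusted p = 0.93) did not pass the test. The trophoblast list passed it without fibroblast replicate 2 (adjusted p = 0.045) or dedifferentiated replicate 1 (0.048), and the mesoderm and endoderm list among genes above the median level (0.033) or with a group mean of at least 6 (0.028). The laminin Lama1 rose by 6.61, the endoderm regulator Sox17 by 2.95 and Pecam1 by 2.44, and Eng fell by 3.68. Of 25 Hox genes, 0 were called by limma in any of the 3 comparisons, and 0 at an unadjusted p under 0.05 with a change of at least 1 log2 unit.

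Imprinted genes went both ways in the dedifferentiated cells. Of 22 measured, 8 were higher and 4 lower than in fibroblasts (adjusted p = 0.21 for the list). Igf2 rose by 3.4, Phlda2 by 4.29 and Dlk1 by 2.22, and Dcn, Ndn and the noncoding RNA Meg3 differed by -6.16, -2.03 and -1.87. Dcn also belongs to the extracellular matrix list, of which 31 of 33 genes were lower, so its fall is not particular to imprinted genes. Among 14 p53 targets and cell-cycle inhibitors, 4 were higher and 2 lower (adjusted p = 0.75), and Cdkn2a differed by 0.2 (adjusted p = 0.091). Of 11 housekeeping genes, 1 was called, Gusb at -1.55 (adjusted p = 0.41 for the list).

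Sex-linked transcripts differed between fibroblasts and both other groups. Xist, the noncoding RNA that coats an inactive X chromosome, was at 7.31 ± 0.074 in fibroblasts, 3.25 ± 0.21 in dedifferentiated cells and 3.15 ± 0.32 in ES cells (log2 mean ± SD, n = 3 each). Eif2s3y, on the Y chromosome, was at 3.55 ± 0.12, 8.09 ± 0.12 and 7.76 ± 0.25 in the same order, and Uty, also Y-linked, at 3.73 ± 0.32, 6.36 ± 0.049 and 5.63 ± 0.18. From fibroblasts to dedifferentiated cells, Xist fell by 4.07 log2 units (adjusted p = 9.8e-10), Eif2s3y rose by 4.54 (adjusted p = 8.2e-11) and Uty rose by 2.63 (adjusted p = 2.7e-08). A further Y-linked gene, Kdm5d, was dim in every group and differed by 0.64 (95% interval 0.35 to 0.92). The adjusted p of this list of 4 measured genes, whose members go opposite ways, was 0.21. Both comparisons with fibroblasts are therefore also comparisons between cells that differ in sex-linked transcripts. Rises and falls from fibroblasts are differences of group means and need not be changes within the same cells.

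**Figure D1:**
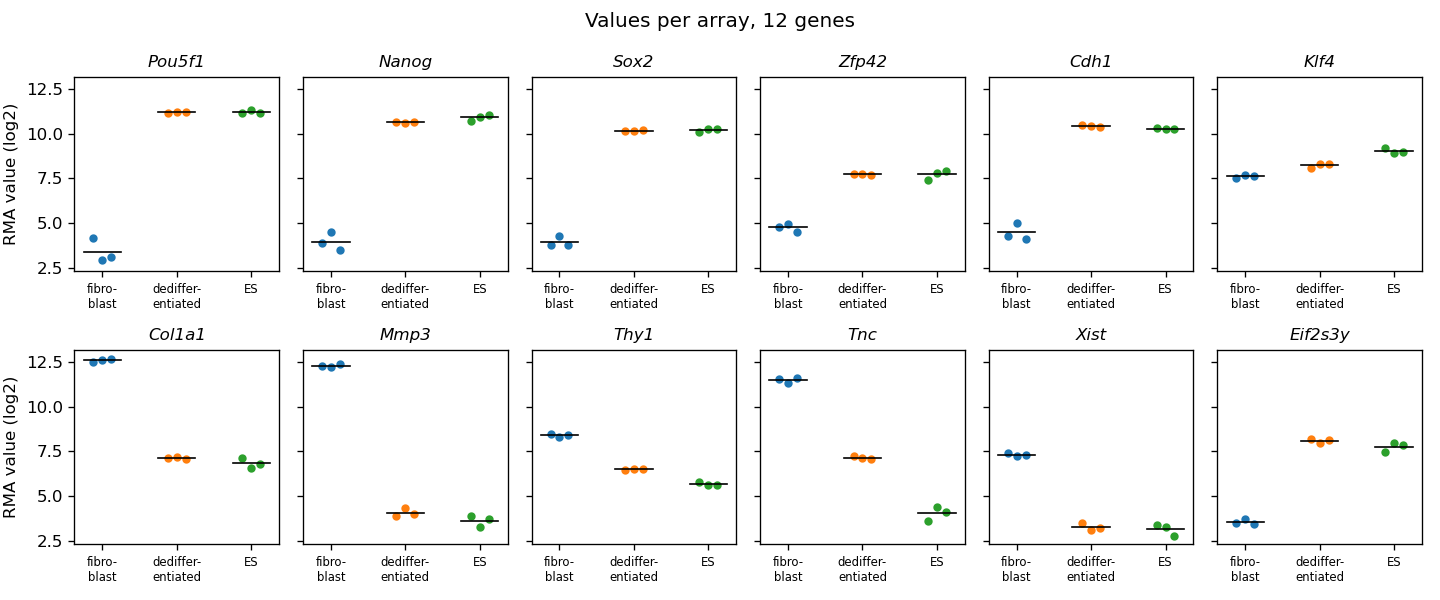
Values of 12 genes on each array (log2, y axis) in fibroblasts, dedifferentiated cells and ES cells (x axis); each point is 1 array and each bar the mean of 3. Pou5f1 lies near 3.39 in fibroblasts and near 11.21 and 11.22 in the other groups, and Xist and Eif2s3y change in opposite directions.

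The second comparison took the ES cells as the reference for pluripotent cells and set them against the same fibroblasts. The ES cells had 1764 genes higher and 2073 lower. Tdgf1 led the rises at 8.17 log2 units (95% interval 7.96 to 8.39), and other large rises were Pou5f1 at 7.82, Dppa5a at 7.76, Nr0b1 at 7.19, Nanog at 6.97 and the stathmin Stmn2 at 6.47. The largest falls were Mmp3 at -8.7, Lox at -8.1, Il6 at -7.7, Serpina3n at -7.55, the matrix glycoprotein Tnc at -7.48 and Ptx3 at -7.38. Klf4 rose by 1.41 and Myc fell by 3.16 (95% interval -3.36 to -2.96).

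By list, all 36 core pluripotency genes were higher in ES cells than in fibroblasts (adjusted p = 2.1e-22, and adjusted p = 0.0069 with an estimated correlation), as were all 17 epithelial genes (adjusted p = 1.1e-12, and adjusted p = 0.022 with an estimated correlation). The extracellular matrix list had 31 of 33 lower (median -5.08, adjusted p = 7.6e-24) and the fibroblast identity list 23 of 27 lower (median -3.21, adjusted p = 2e-18), each with an adjusted p = 0.0069 with an estimated correlation. Prrx1 fell by 5.8, Thy1 fell by 2.73, Tbx20 fell by 6.03 and Myl9 fell by 4.9. Of the interferon genes 17 of 18 were lower (adjusted p = 4.3e-12) and of the cytokine genes 14 of 16 (adjusted p = 9.7e-10), each with an adjusted p = 0.026 with an estimated correlation. Mitosis genes were higher in 15 of 20 cases (median 1.35, adjusted p = 3.9e-10, and adjusted p = 0.17 with an estimated correlation). In all, 18 of 28 lists were called in each comparison with fibroblasts, and 8 of those for dedifferentiated cells and 9 of those for ES cells held with an estimated correlation. Counts of called members adjusted over the list alone equalled those over all genes for each of the 28 lists in all 3 comparisons. The median, mean and test of a list differed in sign for neural ectoderm in dedifferentiated cells against fibroblasts (median 0.07, mean -0.02, tested lower), and for endothelial (median -0.03, mean -0.06, tested higher) and Hox genes (median 0.05, mean -0.02, tested lower) in ES cells against fibroblasts. They also differed for core pluripotency (median -0.01, mean 0.17) and imprinted genes (median -0.02, mean 0.22, both tested higher) in dedifferentiated against ES cells.

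Changes from fibroblasts ran closely parallel in the dedifferentiated and ES cells. Across genes, which are not independent replicates, the log2 changes correlated at Pearson r = 0.955 and Spearman rho = 0.881. Groups simulated without any change, fibroblasts included, gave r = 0.501, since both comparisons share the simulated fibroblast arrays. The covariance was 1.08, against 0.006 in the simulation, a difference of 1.07. Of the genes higher in dedifferentiated cells, 1320 (75.3%) were also higher in ES cells, and of those lower, 1773 (88.1%) were also lower. Independent lists of these sizes would share 155 and 209. The simulation shared 0 and 0, but it held no changed gene and so gives no reference for these overlaps. The 3 fibroblast arrays could not be split into parts of at least 2 each, so part of the excess of these overlaps over independent lists may come from the shared controls. On a scale from the fibroblast mean at 0 to the ES mean at 1, over the 3837 genes called between those groups, the dedifferentiated arrays lay at 0.929 ± 0.0035 and the ES arrays, each placed without itself, at 0.997 ± 0.018 (mean ± SD, n = 3 each). The exact two-sided permutation p was 0.1 for n = 3 against 3, the smallest it can give.

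**Figure D2:**
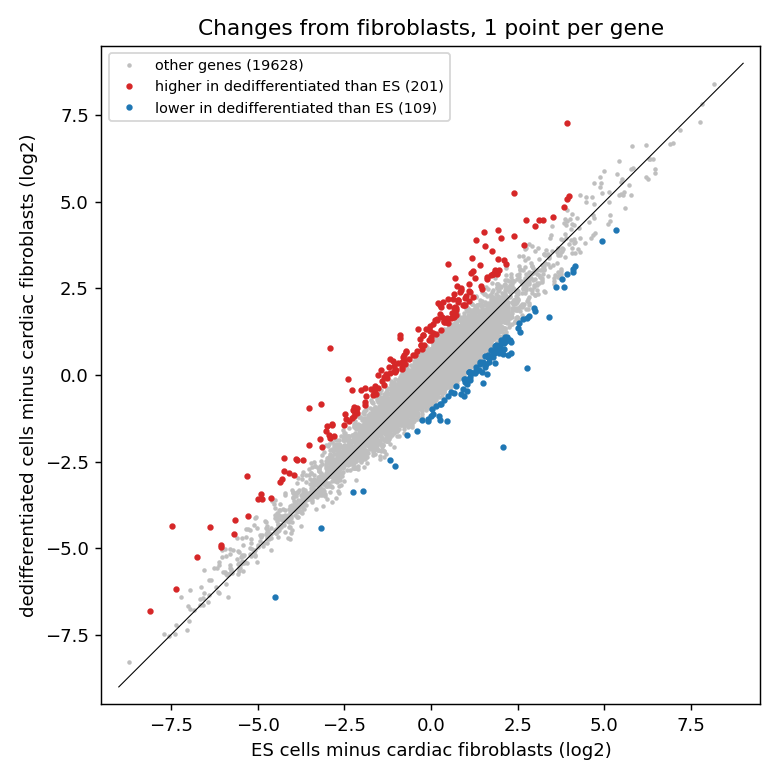
Log2 change from fibroblasts in ES cells (x axis) and in dedifferentiated cells (y axis), 1 point per gene, with the line of equal change. Most points lie along the line (r = 0.955 across genes), and colour marks the 201 genes higher and 109 lower in dedifferentiated than in ES cells.

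The third comparison asked where the dedifferentiated cells differed from ES cells. Pluripotency regulators such as Pou5f1 and Sox2 were at close levels. The difference was 0 for Pou5f1 (95% interval -0.55 to 0.54), -0.05 for Sox2 (-0.33 to 0.23), 0.02 for Zfp42 (-0.3 to 0.33) and -0.29 for Nanog (-0.73 to 0.15). These intervals use the spread of all 3 groups, so the fibroblast arrays widen them (Nanog SD 0.51, against 0.025 in dedifferentiated and 0.17 in ES cells). Nanog lay at 10.61 to 10.66 on the dedifferentiated arrays and at 10.74 to 11.07 on the ES arrays, without overlap. The values of Pou5f1, Sox2 and Zfp42 overlapped. The genes with the largest rises in dedifferentiated cells included Fst, which encodes an activin-binding protein, at 3.69 log2 units (12.9-fold, 95% interval 3.38 to 3.99), Trh at 3.34 and Tnc at 3.11, and Myc rose by 2.31 (2.11 to 2.51). In all, 201 genes were higher and 109 lower, and for 19187 of 19938 genes (96.2%) the 95% interval lay within 1 log2 unit of 0. Among the 3837 genes called between ES cells and fibroblasts, the interval lay within that margin for 3387 (88.3%), and 207 (5.39%) were called between dedifferentiated and ES cells. With a margin of 1.5-fold the numbers were 16087 of all genes and 2271 of the 3837.

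Among core pluripotency genes, 4 of 36 were higher in dedifferentiated cells and 1 lower than in ES cells (adjusted p = 0.24 for the list). Lefty1 and Lefty2, inhibitors of Nodal signalling, rose by 2.2 and 1.93, and the naive-state factor Tfcp2l1 fell by 1.14. Klf4 differed by -0.79 (95% interval -1.01 to -0.57), short of the required size. Of 14 primed epiblast genes, 4 were higher: Zic2 by 1.81, Dnmt3a by 1.68, Otx2 by 1.25 and Dnmt3b by 1.01 (adjusted p = 0.00071 for the list, adjusted p = 0.22 with an estimated correlation, and 0.051 among genes above the median level). Dnmt3b was below the required size without dedifferentiated replicate 1 (0.98) and after another quantile normalization (0.96). Tert, the telomerase reverse transcriptase, fell by 1.14.

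Of 27 genes of fibroblast and mesenchymal identity, 5 were higher in dedifferentiated than in ES cells and 0 lower (median 0.5, adjusted p = 8.9e-11, and adjusted p = 0.0093 with an estimated correlation). The filament protein Vim rose by 1.51, Pdgfra by 1.37, Cd44 by 1.27 and Runx1 by 1.08, while Col1a1 and Col3a1 differed by 0.31 and 0.34 (adjusted p = 0.11 each) and Thy1 by 0.85. Of 33 matrix genes, 4 were higher, including Lox by 1.29 (adjusted p = 2e-06, and adjusted p = 0.062 with an estimated correlation). Among cardiac transcription factors, Gata4 and Gata6, which also act in early endoderm, rose by 1.63 and 1.36 (2 of 12 higher, adjusted p = 0.15 for the list, and 0.045 among genes with a group mean of at least 6). Sox17 and Sox7 were higher by 1.79 and 1.4 in the mesoderm and endoderm list (2 of 19, adjusted p = 0.078, and 0.01 among genes above the median level and 0.0025 among those with a group mean of at least 6). The endothelial cadherin Cdh5 rose by 1.38, Ptgs2 by 2.36, Nes by 2.05, Cnn1 by 1.53 and Inhba by 1.17. The water channel Aqp8, the tetraspanin Tspan8 and the retinoic acid hydroxylase Cyp26a1 were higher by 2.87, 2.7 and 2.61.

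Mitosis genes were slightly lower in dedifferentiated than in ES cells, with 0 of 20 called by limma at the required size, 0 of them at an unadjusted p under 0.05 with that size, but a median of -0.34 (adjusted p = 1.2e-07, and adjusted p = 0.22 with an estimated correlation). DNA replication genes went the other way, with a median of 0.11 and an adjusted p = 0.00036 for the list (adjusted p = 0.3 with an estimated correlation), and 0 of 24 were called by limma, 0 at an unadjusted p under 0.05 with the required size. Epithelial genes had a median of -0.45 (1 of 17 lower, adjusted p = 6.7e-05, and adjusted p = 0.082 with an estimated correlation). The lower gene, Cldn3 at -1.03, was below the required size without dedifferentiated replicate 3 (-0.96), ES replicate 1 (-0.95) or ES replicate 3 (-0.96), and with array weights (-0.85). With clone and model names left out, the largest falls were Septin4 at -2.55, Scel at -1.9, Azin2 at -1.79, Zc3h6 at -1.75, Got1l1 at -1.72 and Pstpip2 at -1.67. Perp differed by -1.29 and Stat2 by -1.58. Dlk1 and Phlda2 were higher by 1.23 and 1.28, and Meg3 differed by -0.07 (95% interval -0.44 to 0.3). Of 28 lists, 12 were called, and 1 of them held with an estimated correlation. With limma's test against a change of 1 log2 unit, 31 genes were higher and 7 lower.

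**Figure D3:**
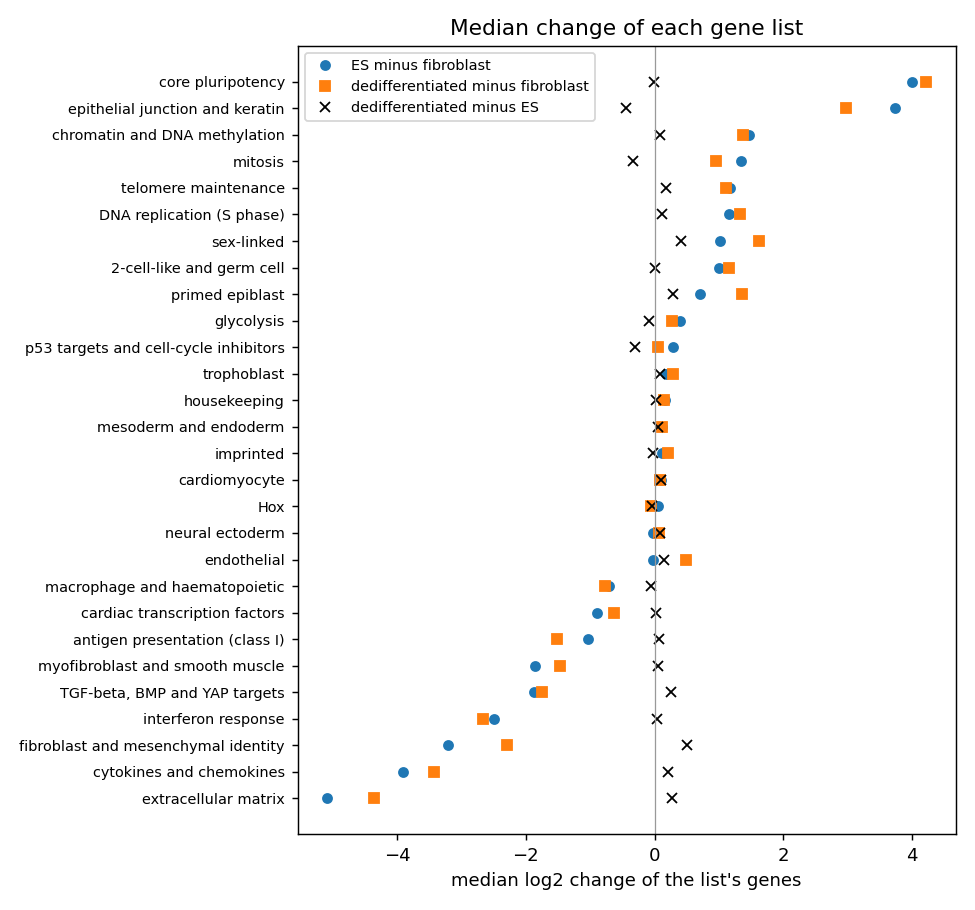
Median log2 change (x axis) of the genes of each fixed list (y axis) for the 3 comparisons, without error bars. Core pluripotency lies at 4.21 and 4 and extracellular matrix at -4.36 and -5.08 against fibroblasts, and the differences between dedifferentiated and ES cells lie near 0.

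Over the 3 groups together, the moderated F test called 4543 genes (22.8%) with a range of group means of at least 1 log2 unit.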

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

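Both kinds of result in this part were chosen after the values were seen. One gene changed in opposite directions from fibroblasts in the dedifferentiated and the ES cells. G530011O06Rik, chosen after its values were seen, differed by -2.09 log2 units in dedifferentiated cells and by 2.08 in ES cells, and the direct comparison of dedifferentiated with ES cells gave -4.17 (limma adjusted p = 1e-07).

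Rows that the comparisons did not use, because they match several genes or none, also held differences from the fibroblasts. Of 13768 such rows, 1093 were higher and 235 lower in dedifferentiated cells, and 946 were higher and 286 lower in ES cells.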

How the results depend on the processing

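Nearly every count kept within 1.5 times its value under another normalization, centring, variance model or array weighting, and no gene named changed direction. Testing all rows of the table gave 3056 higher and 2340 lower for dedifferentiated against fibroblast, and 2900 and 2463 for ES against fibroblast. For dedifferentiated against ES it gave 443 and 190. More rows were tested, but the counts did not rise in step, and the cause was not tested. With no minimum fold the 6 counts were 4977 higher and 4468 lower (dedifferentiated against fibroblast), 5203 and 4570 (ES against fibroblast), and 2236 and 2003 (dedifferentiated against ES). Testing against a change of 1 log2 unit gave 1101 and 1122 genes higher against fibroblasts, and 31 higher and 7 lower against ES cells; this follows from the stricter test.

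Leaving out 1 array gave 1732 to 1791 higher and 1977 to 2052 lower for dedifferentiated against fibroblast, 1705 to 1891 and 2047 to 2152 for ES against fibroblast, 189 to 232 and 82 to 153 for dedifferentiated against ES, and 4539 to 4632 for the 3 groups. The position, 0.929, was 0.924 after another quantile normalization, 0.925 among genes above the median level, 0.949 on linear values and 0.919 to 0.931 without 1 array. The correlation, 0.955, was 0.96 among genes with a group mean of at least 6, 0.935 over all rows, 0.953 with array weights, 0.97 among genes called in either comparison and 0.953 to 0.956 without 1 array. Genes equivalent between dedifferentiated and ES cells numbered 9353 and 8952 under the filters on dim genes and 32143 over all rows, following the number tested, and 19004 to 19189 without 1 array. The cause of the other shifts was not tested.

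List calls fell from 18, 18 and 12 to 8, 9 and 1 with an estimated correlation, and fry gave 21 between dedifferentiated and ES cells; the cause was not tested. The macrophage list turned direction among genes above the median level (median 1.02 for dedifferentiated and 1.75 for ES cells against fibroblasts, adjusted p = 0.6 and 0.41), with fewer genes tested. Of the other list results, 62 lost and 34 gained a call, and of the named-gene results 10 lost and 4 gained one.

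The replicate numbers did not pair the samples: of 9 same-number pairs, 3 had residual correlations over 0.1 (range -0.2 to 0.25), and 3 arrays correlated best with their own number. With a replicate block the counts were 1753 and 2012, 1764 and 2073, and 201 and 109. The arrays carry no detection calls, so signal over background could not be set as a limit.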

Other observations

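The tests of the sex-linked pattern, of residual fibroblasts, of the normalization, of chromosome copies (with a criterion made stricter after a first result) and of the splits of 2 groups were chosen only after the result was seen.

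Genes that set the dedifferentiated cells apart from ES cells were often outside the range of both other groups. Of the 201 genes higher in dedifferentiated than ES cells, 102 were also higher than in fibroblasts and 79 were genes that fibroblasts also had higher than ES cells. Of the 109 genes lower, 17 were also lower than in fibroblasts and 78 were genes that fibroblasts also had lower than ES cells.

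Xist was low and Y-linked transcripts high in the dedifferentiated cells, the reverse of the fibroblasts arrayed beside them. Loss of Xist in cells without a Y chromosome cannot bring Y transcripts, and the 95% interval of the Eif2s3y rise began at 4.26. Eif2s3x, its X-linked homologue, did not rise with it (upper bound of the interval -0.05), although Kdm6a, the homologue of Uty, was higher in dedifferentiated cells (7.23 ± 0.1) than in fibroblasts (5.92 ± 0.3, log2 mean ± SD, n = 3 each). A plain mixture of the arrayed ES cells and fibroblasts is argued against by the 38.4% of 310 genes that lie outside both groups. On the 3 fibroblast arrays Eif2s3y lay at 3.45 to 3.69, and on the 3 dedifferentiated arrays at 7.95 to 8.18. If the sample names are right, these values argue against the bulk of the arrayed fibroblasts as the source of the dedifferentiated cells. Whether the source was male fibroblasts of other animals, a male minority or ES cells changed in culture stays open. Wrong sample names were not tested. The Eif2s3y level of the fibroblasts was 4.31% of the dedifferentiated level, background signal included.

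Genes higher in dedifferentiated than in ES cells included Vim and Pdgfra of the mesenchymal list and Gata4, Gata6 and Sox17, which act in early endoderm. Sox17 was also higher than in fibroblasts, by 2.95 log2 units. Gata4 and Gata6 were not called higher than in fibroblasts (0 of 12 cardiac transcription factors were). Of the genes higher in dedifferentiated than in ES cells, 50.7% also lay above the fibroblast level, which argues against residual fibroblasts as their source. Another 79 of the genes were at least 1 log2 unit higher in fibroblasts than in ES cells. These 79 would need a median fibroblast share of 31.9% (quartiles 11.2 to 67.1). The 100 genes with the largest fall from fibroblasts to ES cells gave 0.343% (quartiles 0.0389 to 1.01). That gap argues against residual fibroblasts for these 79 as a set, although they were chosen as higher in dedifferentiated cells. For the remaining genes residual fibroblasts stay open. A share of extraembryonic endoderm-like cells may contribute: a list of 21 further endoderm markers was higher (median 0.54, camera p = 1.2e-08, and p = 0.055 with an estimated correlation), with 20 above 0 and 3 called, Pth1r, Plat and Ctsh, and its brightest members Lamb1 and Lamc1 at log2 means of 11.78 and 11.6 against 11.1 and 11.03 in ES cells. Of these 21 genes, 8 were higher in fibroblasts than in ES cells, and the endoderm receptors Cubn and Lrp2 differed by -0.08 and 0.09, which leaves this a hypothesis. Culture conditions were not tested.

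Neighbouring genes shifted together on some chromosomes between dedifferentiated and ES cells. Among 9664 genes above the median level, the median was 0.094 on chromosome 8 and -0.134 on chromosome 4, beyond 10000 random lists matched on mean expression (adjusted p = 0.00095 for each, from the smallest p that the lists can give, 1e-04), which argues against an intensity-dependent bias; chromosomes 11 (0.065, adjusted p = 0.0032) and 9 (-0.028, adjusted p = 0.045) were also shifted. At least 4 of 5 blocks of neighbouring genes moved the same way on chromosomes 4 and 8. The blocks of chromosome 4 ranged from -0.376 to 0.042. Chromosomes not shifted beyond the random lists also reached this count. On chromosome 14 it was 5 of 5 (adjusted p = 0.25 against the lists) and on chromosome 6 it was 4 of 5 (adjusted p = 0.43). The block count therefore cannot decide whether a few strongly changed genes made the shifts. An extra copy of chromosome 4 or part of it in the ES cells may account for the shift of chromosome 4 (ES minus fibroblast, adjusted p = 0.0057), while for chromosome 8 an extra copy in dedifferentiated cells stays undecided (adjusted p = 0.11 against fibroblasts). Passing against fibroblasts is not particular to a copy change, since chromosome 11 passed in ES cells (0.188, adjusted p = 0.022) and in dedifferentiated cells (0.211, adjusted p = 0.0019). Both whole-chromosome shifts are small for a copy carried by every cell, but 1 block of chromosome 4 reached -0.376. Of the 659 genes used on chromosome 4, 28 were called lower and 7 higher in dedifferentiated than in ES cells. No other autosome had more than 8 called lower, the number on chromosome 9. Differences in genetic background were not tested.

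For each comparison of 2 groups, 10 splits of the 6 arrays exist, too few for a share under 0.05. The real splits called 3765, 3837 and 310 genes, 1 of 10 splits giving as many each time, and the highest other split called 0 by limma (3, 1 and 5 at an unadjusted p under 0.05 with the required size). For the lists, 2, 2 and 1 of the 10 splits gave as many calls as the real 18, 18 and 12. The other splits gave 12 to 19, 10 to 20 and 3 to 10. Each other split puts 2 arrays of 1 group with 1 of the other. It therefore keeps part of the real difference and has a wider spread within its sets. Neither its list calls nor its 0 genes called by limma are a reference without that difference, so these splits of 2 groups cannot decide about chance. For the F test over 3 groups, 1 of 100 splits, the real grouping itself, gave as many genes as the real 4543. The highest other split still called 4019. The real grouping thus called more genes than every other split drawn. Since the samples of a group may be technical repeats, these splits cannot exclude chance differences between animals or cultures.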
